A study of Arabidopsis thaliana with 12 samples.

How the data were processed

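The series holds 12 one-colour arrays of a custom Agilent Arabidopsis design, 3 biological repeats each of WT plants at 22 °C, xrn4 plants at 22 °C, WT plants after 1 h at 37 °C and xrn4 plants after 1 h at 37 °C. Per the labels, each sample was total RNA of whole 2-week-old plants labelled with Cy3. Per the file headers, the authors extracted spot values with Feature Extraction 10.7.3.1 (protocol GE1_107_Sep09), and the deposited scanner files give an intensity for each of 54778 spots per array, of which 53459 are not controls. The deposited value table gives a ratio for each of 32788 loci, the spot's processed signal over a factor of its array. These factors were read from the files as 153 to 387, at which 75.3 to 75.5% of the probes lie below the factor. The medians of the value table are 0.335 to 0.382. Of the loci with a probe, 32770 matched the scanner signal over the factor within 0.1%, and 11 held the signal of another probe of the locus.

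Background-subtracted, model-corrected processed signals were taken from the scanner files, averaged over copies of a probe (52586 different probes), put on the log2 scale and set relative to the 75th percentile of the array's signals. That percentile was 155 to 396 and the median signal 32.8 to 64.0 scanner units. A probe was kept when the scanner software called it well above background on all 3 arrays of at least 1 group. Of 32788 loci with a probe, 24436 were kept, 20101 of them well above background on all 12 arrays. The brightest kept probe stood for a gene. Symbols came from the reference table, which held 24238 of the kept loci, 9254 with a symbol other than the locus tag. The array design gives no usable genome build, so no coordinates are printed.

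The main model was limma 3.58.1 in R 4.3.3 with 4 group means over all 12 arrays, 8 residual degrees of freedom and a prior of 2.53. The contrasts were xrn4 against WT at 22 °C, xrn4 against WT at 37 °C, heat in WT, heat in xrn4, and the interaction (heat in xrn4 minus heat in WT). Tests were two-sided with Benjamini-Hochberg adjustment over 24436 genes and a threshold of 0.05. A gene that no array of 1 group measured well above background received a bound in place of a fold change. This applied to 88, 143, 601 and 403 of the calls in the pair comparisons. Genes dim in both groups received none, and in list medians that use bounds they were set to 0.

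Gene lists were fixed before the data were examined: small heat shock proteins (16 genes measured), large chaperones (22), heat shock factors (18), unfolded protein response (15), microRNA targets (61), RNA decay (26), ethylene (23), salicylate (16), jasmonate (19), abscisic acid and dehydration (24), oxidative (16), touch and handling (13), auxin (9), photosynthesis (45), clock (15), cell cycle (25), root (18), stomata (7) and xylem (5). Some genes stood in more than 1 list, among them 4 of the touch genes. Each list was tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over 19 lists per comparison, and again with the correlation estimated. The named genes were set by rule: XRN4, HSFA2 and ERF1 always; the 10 highest and 10 lowest log2 fold changes among genes past the threshold whose groups did not overlap (no such demand for the interaction); and up to 4 members per list with the smallest p. Members named by the last part that did not pass, and some of those with the smallest changes, are covered by the counts of their list. The iron genes were chosen after their values were seen. A ribosomal protein list was left out, as it needs gene products that the reference lacks.

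The label numbers of the arrays equal the slide. After removal of group means, the correlation of same-numbered arrays was over 0.1 in 12 of 18 pairs (range -0.006 to 0.320), and for 12 of 12 arrays the closest array of another group had the same number. Every comparison was therefore also fitted with this number as a replicate block, which gave 6041, 5285, 17151, 16254 and 673 genes in the order of the contrasts above.

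The model was tested on simulated data made from the arrays, with 50 genes changed at each size. At log2 sizes of 0.5, 1, 2 and 4 the recovered percentages were 26, 88, 100 and 100 at 22 °C and 28, 72, 98 and 100 at 37 °C. They were 32, 76, 98 and 100 for heat in WT, 28, 72, 100 and 100 for heat in xrn4, and 4, 62, 90 and 100 for the interaction. False calls numbered 4 of 161, 10 of 159, 9 of 162, 6 of 156 and 6 of 134. A shifted list was called in 10 of 10 runs in each comparison, and 1 of 180 unshifted lists was called at 22 °C and 0 of 180 in the others. The simulated genes varied independently of each other and without slide effects. These counts therefore do not measure how often lists of correlated genes are called falsely.

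Alternatives were quantile scaling, median scaling, normexp with an offset of 50 followed by quantile scaling, no filter, a filter for probes well above background on all 12 arrays, the deposited value table, the replicate block, fits of the 6 arrays compared, a variance prior with trend and robust options, the mean of a gene's kept probes, a 2-fold minimum, an estimated correlation for lists, and each array left out. Probes that name no locus and probes tiled across single genes, which include the opposite strand, entered no comparison of genes. Files were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.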

Results

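Arabidopsis plants of the Columbia wild type (WT) and of the mutant atxrn4-3 (xrn4) were compared at 22 °C and after 1 h at 37 °C, with 3 whole-plant samples in each of the 4 groups. XRN4 is the cytoplasmic exoribonuclease that degrades decapped mRNA from its 5′ end. Gene levels are log2 scanner signals relative to the 75th percentile of the same array. Group levels are given as mean ± SD and log2 fold changes as value ± SE, with n = 3 arrays per group. Adjusted p comes from limma over 24436 genes. Every gene named below as having passed moved in the stated direction on 3 of 3 slides. For the highest and lowest genes of the pair comparisons, the demand that groups not overlap fixed this in advance. Between replicate arrays the correlation across genes was 0.986 to 0.994, and the SD of the difference was 0.266 to 0.423 on the log2 scale. The spots well above background made up 58.5 to 72.9% of an array, and 0 spots were saturated. Each slide held 1 array of every group, so every comparison could be made within slides. Array position on the slide was fixed for each group, so position and group cannot be told apart.

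XRN4 (AT1G54490) was at 0.42 ± 0.07 in unheated WT plants and at -4.35 ± 0.30 in unheated xrn4 plants, where 2 of 3 arrays measured it well above background. The genotype difference was -4.77 ± 0.15 at 22 °C (adjusted p = 1.58e-07) and -3.45 ± 0.15 at 37 °C (adjusted p = 4.55e-06). After normexp and quantile the differences were -2.28 and -1.96. Where the probe lies relative to the insertion is not known, so its signal need not measure functional transcript. The change of XRN4 with heat in WT did not pass (-0.30 ± 0.15, n = 3 per group, adjusted p = 0.0935), though it did with a replicate block (adjusted p = 0.029). Heat raised it by 1.02 ± 0.15 in xrn4 (adjusted p = 0.000164). That difference in heat response passed (1.32 ± 0.21, adjusted p = 0.015) but rests on mutant signals near background. It was 0.83 under quantile scaling (adjusted p = 0.012) and 0.32 after normexp and quantile (adjusted p = 0.106), where the rise in xrn4 was 0.07 (adjusted p = 0.409). HSFA2 (AT2G26150), a heat-induced transcription factor that prolongs the heat response, stood at -2.90 ± 0.26 in WT and -1.94 ± 0.27 in xrn4 at 22 °C, a rise of 0.95 by its brightest probe (adjusted p = 0.00314) and of 0.36, which did not pass, by the mean of its kept probes (adjusted p = 0.126). At 37 °C it stood at 9.21 ± 0.12 and 8.78 ± 0.16, a difference of -0.43 that did not pass (adjusted p = 0.0948). ERF1 (AT3G23240), an ethylene and jasmonate response factor, was 2.21 ± 0.28 higher in xrn4 at 22 °C (adjusted p = 0.000664). At 37 °C its difference of 0.65 ± 0.28 did not pass (adjusted p = 0.135).

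**Figure D1:**
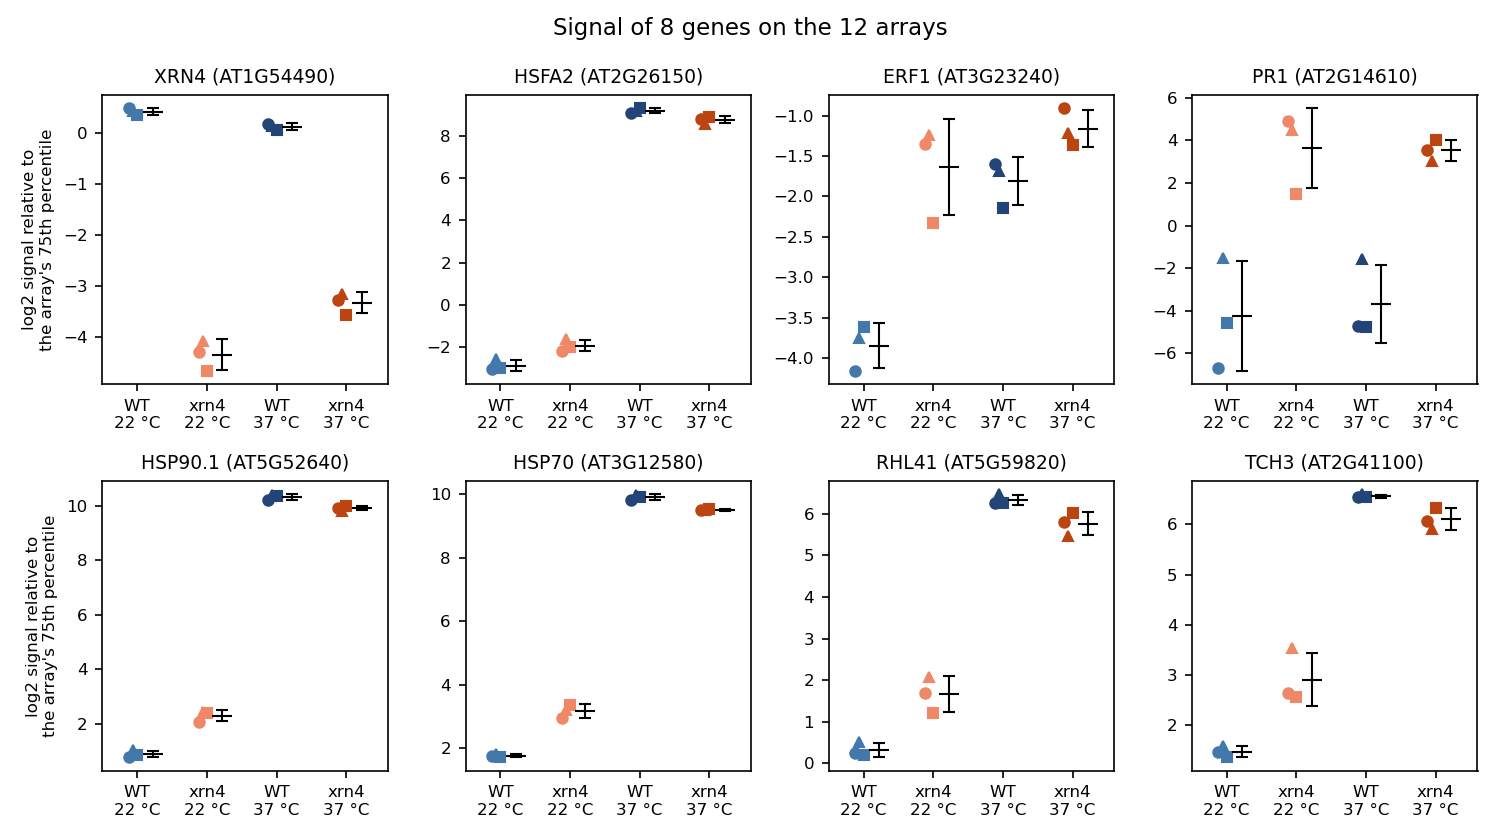
Log2 signal relative to the 75th percentile of the array (vertical axis) for 8 genes in WT and xrn4 plants at 22 °C and 37 °C; circles, triangles and squares are replicates 1, 2 and 3, and bars are the mean ± SD of 3 arrays. XRN4 lies at 0.42 in unheated WT and -4.35 in unheated xrn4, and HSP90.1, HSP70, RHL41 and TCH3 are higher in xrn4 than in WT at 22 °C.

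Unheated xrn4 plants carried far more transcript of single salicylate and jasmonate defence genes than unheated WT plants. PR1 (AT2G14610), the standard marker of salicylate defence, was 7.89 ± 1.325 higher (adjusted p = 0.00292), from -4.26 ± 2.58 to 3.63 ± 1.88, and 1 of 3 WT arrays measured it well above background. NATA1, a jasmonate-induced ornithine acetyltransferase, rose by 5.95 ± 0.74 (adjusted p = 0.000636). The senescence gene SAG13 rose by 4.99, the peroxidase PRX52 by 4.59, the glucanase gene BGL2 by 4.59 and the aminotransferase TAT3 by 4.41. Of these 4, WT arrays measured SAG13 on 3 of 3, PRX52 and TAT3 on 2 of 3 and BGL2 on 1 of 3. WT_control replicate 2 had the highest value of the 3 WT arrays for all 6 genes, and without it PR1 was 9.25 higher, BGL2 and TAT3 5.82 each and NATA1 6.70. Other arrays left out made rises smaller. Without WT_control replicate 1 PR1 was 6.68 higher and BGL2 3.61, and without WT_control replicate 3 PRX52 was 3.97 higher and TAT3 3.56. AT1G26390 rose by 5.41 and AT1G13470 by 4.60, each measured on 1 of 3 WT arrays. AT2G04070 was at least 6.32-fold higher and AT1G36622 at least 8.98-fold higher, as 0 of 3 WT arrays measured them. Such a bound sets the dim group on each array to no less than the lowest level among probes well above background there (-4.81 to -3.10), then compares the group means.

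The genes most reduced in unheated xrn4 plants included genes of chlorophyll synthesis, sulfate transport and an iron-sulfur protein. MRD1 (AT1G53480) fell by 3.12 ± 0.24 (adjusted p = 5.92e-05), AT5G03090 fell by 3.04 and NEET, which encodes an iron-sulfur cluster protein, fell by 2.11 ± 0.31 (adjusted p = 0.00159). The endoplasmic reticulum small heat shock gene ATHSP22.0 fell by 2.32, with 1 of 3 xrn4 arrays measuring it. Lower bounds applied to genes that no xrn4 array measured at 22 °C. CHAT, which makes a leaf volatile ester, was at least 3.92-fold lower, and the root sulfate transporter SULTR1;1 at least 3.41-fold. PORA, a chlorophyll synthesis gene, was at least 3.00-fold lower, AT3G08885 at least 2.83-fold and AT3G49765 at least 1.91-fold.

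Across all genes, 4888 of 24436 differed between the genotypes at 22 °C, 2255 higher and 2633 lower in xrn4 (46.1% higher). Under median scaling the balance turned, to 2146 higher and 1868 lower (53.5% higher). The count was 3089 without WT_control replicate 2, 3149 without WT_control replicate 1 and 3239 without xrn4_control replicate 1. At least 2-fold differences numbered 850, of which 633 were higher. With slide as a replicate block 6041 genes passed, 4761 of them among the 4888. The differences on single slides correlated across genes at 0.65 to 0.76, though genes are not independent replicates, and 99.8% of the calls had 1 sign on all slides. The groups did not overlap for 4851 of the 4888 calls, which alone fixes their sign on every slide. The 2 groups of 3 arrays did not overlap for 41.6% of genes, where chance gives 10%.

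Salicylate genes gave the largest list shift at 22 °C. Of 16 measured, 11 rose (12 adjusted over the list alone) and the median was 1.22, from 1.32 to 1.5 on the 3 slides. FRK1 rose by 2.05, FMO1 by 2.04 (adjusted p = 5.59e-05), CBP60G by 1.98 and WRKY70 by 1.91. The camera test over 19 lists gave the salicylate genes adjusted p = 1.21e-08, and adjusted p = 0.117 with an estimated correlation. Among 19 jasmonate genes 12 rose (14 adjusted over the list alone), with LOX4 up 1.86, LOX3 up 1.60, AOC1 up 1.11 and JAZ1 up 0.92. Their median was 0.56 (adjusted p = 1.1e-08, and adjusted p = 0.0657 with an estimated correlation). Of 23 ethylene genes 9 rose (11 adjusted over the list alone), led by PR4 at 2.35, ERF2 at 1.35 and TEM1 at 0.69. The ethylene median was 0.40 (adjusted p = 7.09e-06, and adjusted p = 0.117 with an estimated correlation). That list holds genes of ethylene signalling as well as genes of the response.

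Of the large chaperones and co-chaperones, 10 were higher in xrn4 before any heat. HSP70 (AT3G12580) was up 1.42 ± 0.10 (adjusted p = 5.59e-05), HSP90.1 (AT5G52640) 1.41 ± 0.11 (adjusted p = 6.97e-05), AT3G09440 1.32 and HSP81-3 0.78. Of 22 large chaperones and co-chaperones 10 rose and 0 fell (12 and 0 adjusted over the list alone). Their median was 0.28, from 0.24 to 0.35 on the slides (adjusted p = 5.32e-07, and adjusted p = 0.171 with an estimated correlation). Touch and handling genes shifted as well, 7 of 13 rising (9 up and 1 down adjusted over the list alone), with STZ up 1.55, TCH3 up 1.44, WRKY40 up 1.41 and WRKY33 up 1.08. The touch median was 0.52, from 0.58 to 0.87 on single slides (adjusted p = 1.87e-05, and adjusted p = 0.117 with an estimated correlation). Endoplasmic reticulum chaperones rose in 4 of 15 cases (9 adjusted over the list alone): BIP3 by 2.41 with 2 of 3 WT arrays measuring it, CRT1b by 0.40, CNX1 by 0.38 and BIP2 by 0.32. That list had a median of 0.30 (adjusted p = 7.87e-05, and adjusted p = 0.178 with an estimated correlation). RNA decay genes other than XRN4 rose in 4 of 26 cases (4 adjusted over the list alone), the deadenylase genes CAF1b by 1.21 and CAF1a by 1.07, AT1G77680 by 0.86 and AT3G61240 by 0.31. Their median was 0.09 (adjusted p = 0.0226, and adjusted p = 0.313 with an estimated correlation). The RNA decay call ended under quantile scaling (adjusted p = 0.111).

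Lists of photosynthesis, cell-cycle, root and xylem genes shifted down in unheated xrn4 plants at the preset correlation. RBCS2B, a Rubisco small subunit gene, fell by 1.3, PSAF by 0.94, LHB1B1 by 0.88 and PSAD-2 by 0.84. Of 45 photosynthesis genes 20 fell (31 adjusted over the list alone). Their median was -0.38, between -0.41 and -0.34 on the slides (adjusted p = 9.82e-09, and adjusted p = 0.317 with an estimated correlation). Root markers fell in 10 of 18 cases (11 adjusted over the list alone), with MYB66 down 1.06, CASP2 down 1.01 and PHT1;1 down 0.83. The root median was -0.67, between -0.71 and -0.46 on the slides (adjusted p = 3.62e-06, and adjusted p = 0.178 with an estimated correlation). In the cell-cycle list 14 of 25 fell and 1 rose (17 and 1 adjusted over the list alone), including CDKB1;2 at -0.56, CDC20.1 at -0.55 and SYP111 at -0.51. That median was -0.32 (adjusted p = 4.72e-05, and adjusted p = 0.151 with an estimated correlation). Of 5 xylem genes 4 fell (4 adjusted over the list alone): CESA4 by 0.57, XCP1 by 0.51, XCP2 by 0.49 and IRX3 by 0.43. The xylem median was -0.49 (adjusted p = 0.00235, and adjusted p = 0.117 with an estimated correlation). The lists of root and xylem genes, chosen as markers of tissue composition, thus shifted in the same direction as those of photosynthesis and cell-cycle genes. The share of each tissue was not itself measured.

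The other 8 lists showed no shift at 22 °C that passed. Small heat shock genes split, 4 up and 3 down of 16 (5 and 5 adjusted over the list alone), with AT5G51440 at 1.59, AT1G59860 at 0.79 and AT1G53540 at -1.42. Their median was -0.15 (-0.03 with genes too dim for a bound set to 0) and their mean -0.26, while the test leaned upward (adjusted p = 0.657). MicroRNA targets split 8 up and 5 down of 61 (8 and 5 adjusted over the list alone, adjusted p = 0.215). The miRNA-controlled genes CSD1, ARF10, CSD2 and AGO2 rose by 1.67, 1.15, 0.98 and 0.88. Heat shock factors had 3 up and 1 down of 18 (4 and 1 adjusted over the list alone, adjusted p = 0.342), HSF A4A up 0.75 and AT-HSFB2B up 0.33. Of 24 abscisic acid genes HAI1 rose by 1.05 and COR15B fell by 1.52 (list adjusted p = 0.396). For oxidative genes 5 of 16 rose and 3 fell (6 and 3 adjusted over the list alone, adjusted p = 0.124). ZAT7 rose by 2.04, RHL41 by 1.34 and MBF1C by 0.92, against FSD1 at -0.98. Auxin genes (adjusted p = 0.657) held IAA2 at 0.61, YUC8 at -0.66, IAA19 at -0.46 and PIF4 at -0.45. Clock genes (adjusted p = 0.467) held LHY at 1.21, ELF4 at -0.94, RVE8 at 0.70 and GI at -0.58. Of 7 stomatal genes FMA rose by 0.43 (list adjusted p = 0.467). The miRNA median was -0.01 with a mean of 0.07, and the abscisic acid median 0.04 with a mean of -0.02, while both tests leaned upward.

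**Figure D2:**
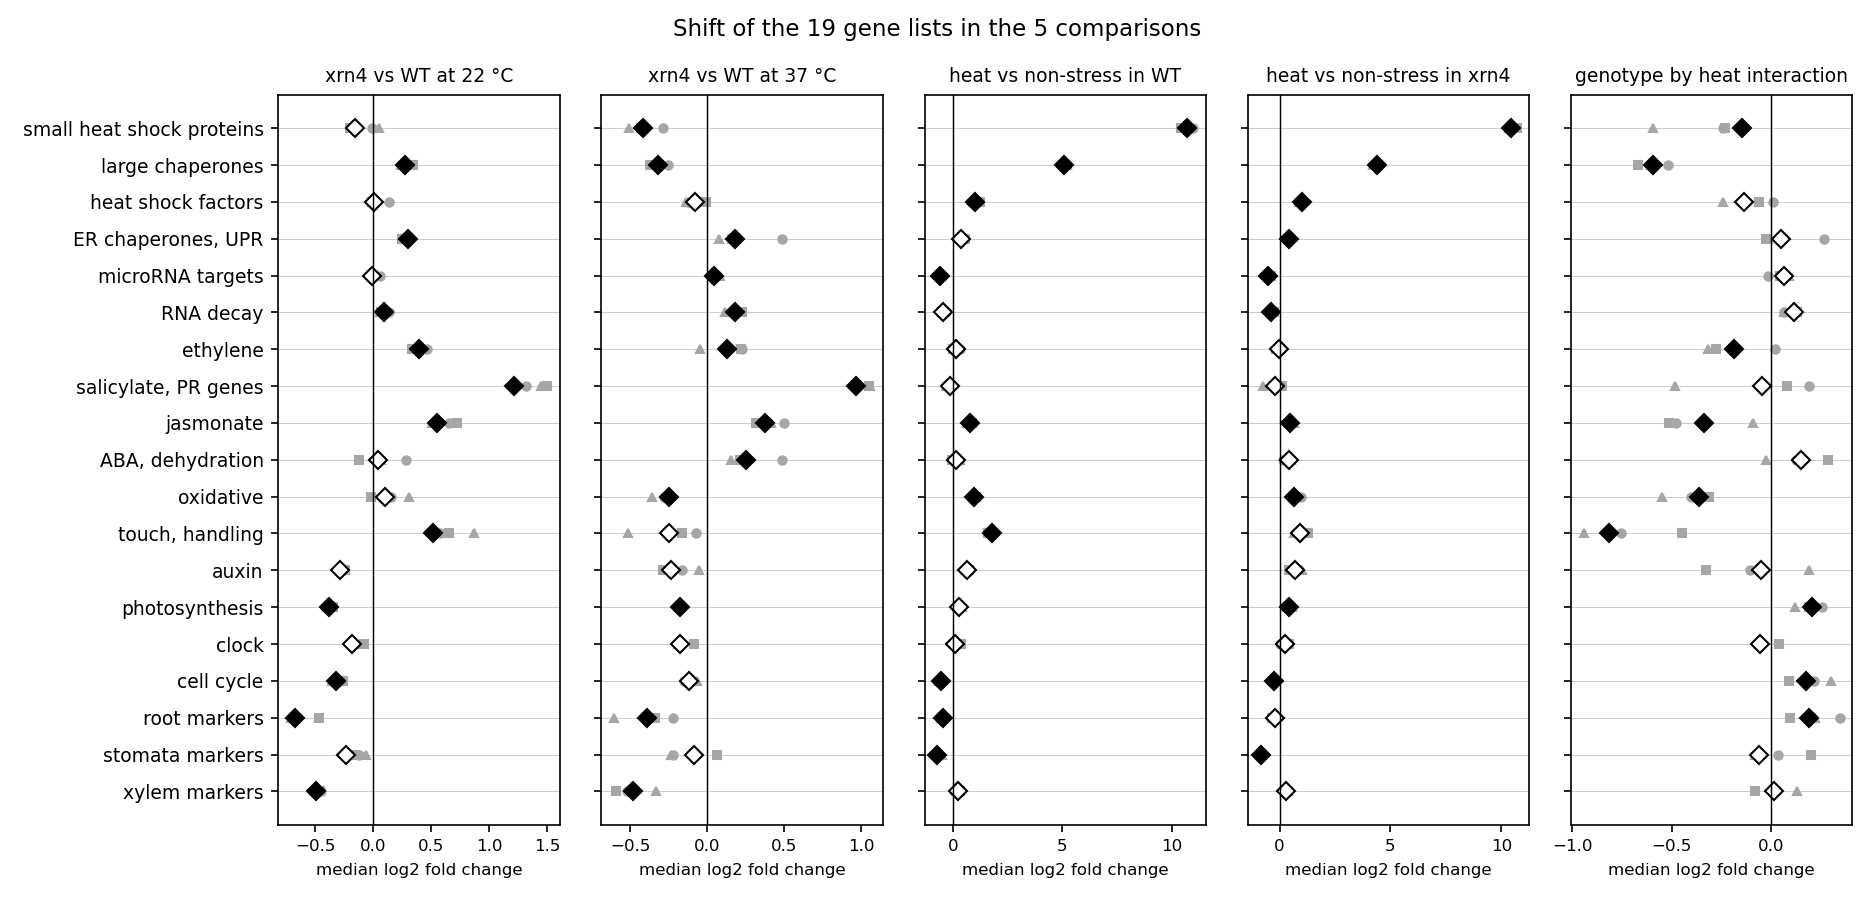
Median log2 fold change (horizontal axis) of 19 gene lists in 5 comparisons; diamonds are medians over all 12 arrays, filled where the camera test with its preset correlation passed, and grey marks are the medians within each of 3 slides. Salicylate genes lie at 1.22 at 22 °C and large chaperones at -0.59 in the interaction, with all 3 slides on the same side.

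Single defence genes were also higher in xrn4 after 1 h at 37 °C. PR1 was 7.21 ± 1.325 higher (adjusted p = 0.00553), with 1 of 3 heated WT arrays measuring it, and TAT3 was 6.09 higher, also measured on 1 of 3. BGL2 was at least 30.3-fold higher, AT1G26390 at least 10.3-fold, AT1G58320 at least 8.00-fold, PRX52 at least 6.15-fold and the alternative oxidase AOX1D at least 5.48-fold. CYP71A13, an enzyme of camalexin synthesis, rose by 4.58 (1 of 3 WT arrays), LURP1 by 4.23 (2 of 3) and SAG13 by 4.08 (2 of 3). Without xrn4_heat replicate 1 the SAG13 rise was 3.34, and without WT_heat replicate 2 the PR1 rise was 8.27. On the lower side, the ferritin gene FER1 fell by 2.2 ± 0.20 (adjusted p = 0.000197), MRD1 by 2.83 ± 0.24 (adjusted p = 0.000134), AT5G03090 by 2.58 and NEET by 1.82. AT5G62730 was at -2.21, AT1G67105 at -2.02 and AT5G46890 at -1.96. AT3G49765 was at least 2.37-fold lower and AT5G51490 at least 2.11-fold.

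At 37 °C, 4142 genes differed between the genotypes, 2341 higher and 1801 lower in xrn4, with 602 at least 2-fold (471 higher). The count was 2487 without WT_heat replicate 3, 2560 without xrn4_heat replicate 1 and 1874 in a fit of the 6 heated arrays alone. The higher share was 56.5%, against 67.3% under quantile scaling and 69.5% under median scaling. With slide as a replicate block 5285 passed, 4029 of them shared. Single slides correlated at 0.47 to 0.56 across genes, and groups did not overlap for 35.3% of genes (chance 10%). Of the calls at both temperatures, 955 were higher in both (216 expected), 896 lower in both (194.1 expected) and 97 opposite (418.4 expected). The log2 fold changes at the 2 temperatures correlated at 0.62 across genes.

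The heat shock lists pointed down in xrn4 at 37 °C. HSP18.2 was at -0.56, AT2G29500 at -0.43 and AT1G54050 at -0.35, the 3 small heat shock genes that fell (3 adjusted over the list alone). The small list median was -0.42 (adjusted p = 0.00363, and adjusted p = 0.288 with an estimated correlation). Among large chaperones Hsp70b fell by 0.53, HSA32 by 0.48, AT5G48570 by 0.47 and CLPB3 by 0.43, within 10 of 22 that fell and 1 that rose (14 and 1 adjusted over the list alone). Their median was -0.32, from -0.37 to -0.25 on the slides (adjusted p = 0.000149, and adjusted p = 0.288 with an estimated correlation). Both calls ended under quantile scaling, with medians of -0.16 and -0.10 (adjusted p = 0.195 and 0.06). Oxidative genes were lower too, 4 of 16 falling (7 adjusted over the list alone): FSD1 by 1.05, APX2 by 0.72, APX1 by 0.52 and FSD2 by 0.44. The oxidative median was -0.25 (adjusted p = 0.00616, and adjusted p = 0.263 with an estimated correlation), and -0.10 under quantile scaling (adjusted p = 0.0624).

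Lists of salicylate, unfolded protein and RNA decay genes shifted up in heated xrn4 plants at the preset correlation. WRKY54 was at least 2.12-fold higher, FMO1 rose by 2.1 (adjusted p = 6.26e-05) and PBS3 by 1.74, among 8 of 16 salicylate genes that rose (11 adjusted over the list alone). The salicylate median was 0.97, or 0.90 with unmeasured genes at their bounds, and 0.98 to 1.06 on single slides (adjusted p = 3.58e-06, and adjusted p = 0.263 with an estimated correlation). BIP3 rose by 2.94 (3.63 without WT_heat replicate 2) and NAC103 by 2.03, each measured on 1 of 3 WT arrays. PDIL1-1 rose by 0.57 and CNX1 by 0.48, among 6 of 15 unfolded protein genes that rose (7 adjusted over the list alone). That list had a median of 0.18 (adjusted p = 0.000386, and adjusted p = 0.263 with an estimated correlation). RNA decay genes rose in 7 of 26 cases and fell in 1 (10 and 1 adjusted over the list alone). AT1G77680 rose by 0.76, AT3G61240 by 0.57, AT3G58560 by 0.44 and LSM1B by 0.43. Their median was 0.18 (adjusted p = 0.00363, and adjusted p = 0.263 with an estimated correlation). MicroRNA targets rose in 9 of 61 cases and fell in 1 (9 and 1 adjusted over the list alone), with the auxin response factors ARF17 up 1.51 (adjusted p = 6.26e-05) and ARF10 up 1.35, CSD2 up 0.78 and HAM2 up 0.52. Their median was 0.05 (adjusted p = 0.0344, and adjusted p = 0.361 with an estimated correlation).

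Jasmonate, ethylene and abscisic acid genes leaned upward at 37 °C. CORI3 rose by 1.63, LOX2 by 1.23, AOC1 by 1.07 and AOC2 by 1.00, among 7 of 19 jasmonate genes that rose and 1 that fell (9 and 2 adjusted over the list alone). The jasmonate median was 0.38 (adjusted p = 0.00575, and adjusted p = 0.263 with an estimated correlation). PDF1.2 rose by 1.82, EBF1 by 0.65, EBF2 by 0.53 and EIL1 by 0.44, among 5 of 23 ethylene genes up and 1 down (5 and 1 adjusted over the list alone). The ethylene median was 0.13, 0.05 with genes too dim for a bound set to 0, and -0.05 on the second slide. The camera test gave the ethylene genes adjusted p = 0.0439, and adjusted p = 0.411 with an estimated correlation. Their call ended under quantile scaling (adjusted p = 0.0576). As the list mixes signalling and response genes, its shift does not by itself mean more ethylene response. ABI2 rose by 0.51, RD22 by 0.48 and ABI1 by 0.39, and CYP707A3 fell by 0.61, within 3 up and 1 down of 24 (5 and 1 adjusted over the list alone). The abscisic acid median was 0.25 (adjusted p = 0.0373, and adjusted p = 0.541 with an estimated correlation). With slide as a replicate block 11 of the 13 list calls at 37 °C held, and the ethylene and abscisic acid calls did not (both adjusted p = 0.0516).

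Lists of root and xylem markers also shifted down in xrn4 at 37 °C. CASP2 fell by 1.02, HKT1 by 0.81 and MYB66 by 0.74, among 7 of 18 root genes (7 adjusted over the list alone). The root median was -0.39 (adjusted p = 0.0122, and adjusted p = 0.46 with an estimated correlation). Xylem genes fell in 4 of 5 cases (4 adjusted over the list alone), CESA4 by 0.64, XCP1 by 0.61, XCP2 by 0.48 and IRX3 by 0.34. Their median was -0.48 (adjusted p = 0.00363, and adjusted p = 0.263 with an estimated correlation). Photosynthesis genes had RBCS2B at -0.81, PSAN at -0.58, LHB1B1 at -0.49 and LHCB2.2 at 0.57, with 4 of 45 down and 1 up (2 and 1 adjusted over the list alone). Their median of -0.17 (adjusted p = 0.0166, and adjusted p = 0.573 with an estimated correlation) flipped to 0.03 under quantile scaling and 0.04 after normexp and quantile. The 6 lists that did not pass were heat shock factors (adjusted p = 0.472, HSF A4A at 0.51), touch genes (0.242), auxin (0.168), clock (0.168), cell cycle (0.299) and stomata (0.168). Within them TCH4 fell by 0.80, DREB1A by 0.64, TCH2 by 0.51, BRU6 by 1.07, PRR5 by 0.75, ELF4 by 0.50, CDC20.1 by 0.54 and SPCH by 0.32, and TSO2 rose by 0.66. HSFA3 fell by 0.41.

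Heat raised 15 of 16 small heat shock genes and single heat shock factors in WT. HSFA2 rose by 12.10 ± 0.16 (adjusted p = 1.43e-12), AT1G59860 by 11.98, HSP17.6A by 11.86, ATHSP22.0 by 11.75, AT1G53540 by 11.34 and HSP17.6II by 11.18. The chloroplast HSP21 rose by 11.93 (1 of 3 unheated arrays measured it) and AT1G71000 by 10.94 (2 of 3). The mitochondrial HSP23.6-MITO was at least 4586-fold higher and the factor AT-HSFA7B at least 1693-fold. The expansin gene EXPA1 fell by 4.29 ± 0.16 (adjusted p = 4.3e-09), AT3G44450 by 4.42 and AT5G10390 by 4.15. Bounds held for AT2G23200 (at least 11.1-fold lower), AT1G08280 (10.3-fold), AT5G26790 (7.73-fold), BBX30 (7.24-fold), NIMIN-2 (6.48-fold), AT2G43445 (6.45-fold) and TINY2 (5.75-fold).

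In WT 16289 genes changed with heat, 8515 up and 7774 down, with 5200 at least 2-fold (2108 up). Slide as a replicate block gave 17151, 16131 of them shared. The rising share was 52.3%, and 36.6% under quantile scaling, which shifted the median of all genes by -0.23 in WT and -0.20 in xrn4 relative to the percentile scaling (normexp and quantile, -0.17 and -0.14). The slides correlated at 0.90 to 0.92 across genes, and groups did not overlap for 72.6% of genes (chance 10%). ERF1 rose by 2.04 (adjusted p = 8.26e-05).

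Of 16 small heat shock genes 15 rose in WT (15 adjusted over the list alone), with a median of 10.71 (adjusted p = 1.92e-13, and adjusted p = 0.051 with an estimated correlation). Large chaperones rose in 20 of 22 cases (20 adjusted over the list alone), Hsp70b by 10.29, HSP90.1 by 9.43, HSA32 by 8.15 and CLPB4 by 6.50. Their median was 5.08 (adjusted p = 1.39e-16, and adjusted p = 0.051 with an estimated correlation). Heat shock factors had 10 of 18 up and 3 down (10 and 3 adjusted over the list alone). HSFA7A rose by 6.67 and AT-HSFB2B by 5.07. Their median was 0.98 (adjusted p = 0.00771, and adjusted p = 0.0574 with an estimated correlation). Oxidative genes rose in 12 of 16 cases (12 up and 1 down adjusted over the list alone). APX2 rose by 9.17, MBF1C by 8.08, DREB2A by 6.65 and GolS1 by 6.51. That median was 0.95 (adjusted p = 0.00012, and adjusted p = 0.051 with an estimated correlation), but 0.10 under quantile scaling (adjusted p = 0.00257) and 0.12 after normexp and quantile (adjusted p = 0.00105). The mean of the oxidative list was 2.925. Whether its rise is separate from that of the heat shock lists was not tested. Touch genes rose in 8 of 13 cases and fell in 2 (8 and 2 adjusted over the list alone). RHL41 rose by 6.0, TCH4 by 5.94, TCH3 by 5.08 and STZ by 3.64. The touch median was 1.76 (adjusted p = 0.0149, and adjusted p = 0.311 with an estimated correlation). Jasmonate genes rose in 11 of 19 cases and fell in 1 (11 and 1 adjusted over the list alone). JAZ7 rose by 4.18 with 1 of 3 unheated arrays measuring it, JAZ10 by 2.74, JAZ5 by 2.50 and TIFY7 by 2.02. Their median was 0.78 (adjusted p = 0.00713, and adjusted p = 0.176 with an estimated correlation).

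Lists of cell-cycle genes, microRNA targets, root markers and stomatal genes shifted down with heat in WT. In the cell-cycle list 18 of 25 fell and 1 rose (18 and 2 adjusted over the list alone). MCM2 fell by 1.35, MCM3 by 1.22, CYCB1;1 by 1.16 and CYC1BAT by 2.83 with 1 of 3 heated arrays measuring it. Their median was -0.57 (adjusted p = 0.000136, and adjusted p = 0.162 with an estimated correlation). MicroRNA targets fell in 32 of 61 cases and rose in 11 (32 and 12 adjusted over the list alone). The leaf growth factors TCP3 fell by 2.49 and TCP4 by 1.76 and HAM2 by 1.48, while AGO2 rose by 2.88. Their median was -0.61 (adjusted p = 0.00153, and adjusted p = 0.166 with an estimated correlation). Root markers fell in 11 of 18 cases and rose in 2 (11 and 2 adjusted over the list alone). EXPA18 fell by 1.61, SHV2 by 1.58 and SCR by 1.32. The root median was -0.48 (adjusted p = 0.0287, and adjusted p = 0.513 with an estimated correlation), and this call ended under quantile scaling (adjusted p = 0.0729). Stomatal genes fell in 6 of 7 cases and rose in 1 (6 and 1 adjusted over the list alone). MYB60 fell by 1.08, FMA by 0.76 and SPCH by 0.73. Their median was -0.72 (adjusted p = 0.0429, and adjusted p = 0.162 with an estimated correlation), and that call also ended under quantile scaling (adjusted p = 0.103).

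The remaining 9 lists did not pass in WT, though single members changed. Unfolded protein genes went 10 up and 4 down of 15 (adjusted p = 0.0613), with ATERDJ3A at least 61.3-fold higher, BIP1 up 1.89, SDF2 up 1.52 and BIP2 up 1.38. RNA decay genes went 6 up and 13 down of 26 (6 and 14 adjusted over the list alone, adjusted p = 0.0517), AT3G58560 at -1.24, AT3G61240 at -1.01, DCP5 at -0.92 and PEL1 at 0.84. Ethylene genes (adjusted p = 0.565) held ERF6 at 2.1, ERF2 at 1.44, ACS6 at 1.4 and EDF3 at -1.92. Salicylate genes (adjusted p = 0.582, median -0.03 with genes at their bounds) held WRKY70 at 2.2, PBS3 at -2.21 and WRKY54, which was at least 5.66-fold lower. Abscisic acid genes split 10 up and 10 down of 24 (adjusted p = 0.625), CYP707A3 at 2.83, RD26 at 2.26, ERD10 at 1.57 and ABF2 at -1.08. Auxin genes (adjusted p = 0.0714) held BRU6 at 2.78, WES1 at 1.89, IAA2 at 1.29 and PIF4 at 1.23. Clock genes (adjusted p = 0.472) held RVE1 at 1.96, PRR7 at 1.83, PCL1 at 1.61 and FKF1 at -1.50. Xylem genes (adjusted p = 0.581) held IRX1 at -0.79, XCP1 at 0.44 and XCP2 at 0.48, the last of which was at -0.00 after normexp and quantile. Photosynthesis genes (20 up and 9 down of 45, median 0.28, adjusted p = 0.404) held LHCB2.2 at -2.21, PSBY at -1.64 and PETE1 at 1.07. The photosynthesis median turned to -0.63 under quantile scaling (adjusted p = 3.08e-05) and -0.64 after normexp and quantile (adjusted p = 1.06e-05).

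Heat raised 15 of 16 small heat shock genes and single heat shock factors in xrn4 too. HSFA2 rose by 10.72 ± 0.16 (adjusted p = 4.47e-12), AT1G53540 by 12.29, HSP17.6II by 11.67, HSP17.6A by 11.65, HSP17.4 by 11.12 and AT1G59860 by 10.93. ATHSP22.0 rose by 13.37, HSP21 by 12.57 and AT1G71000 by 11.50, each measured on 1 of 3 unheated arrays. HSP23.6-MITO was at least 4140-fold higher and AT-HSFA7B at least 1586-fold. The cytokinin synthesis gene IPT3 was at -3.88 and ASG4 at -4.13, each with 1 of 3 heated arrays measuring it, and AT5G20670 at -3.88 (2 of 3). BBX30 was at least 18-fold lower, AT5G26790 9.92-fold, AT2G43445 8.34-fold and CYP707A2, an abscisic acid hydroxylase gene, 7.45-fold. The bounds were 5.11-fold for AT2G22590, 5.02-fold for AT5G55340 and 4.53-fold for AT2G23270. ERF1, at 0.48, did not pass (adjusted p = 0.152).

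In xrn4 15378 genes changed with heat, 8237 up and 7141 down, with 4563 at least 2-fold (2196 up). Slide as a replicate block gave 16254, 15204 of them shared. The rising share was 53.6%, and 36.7% under quantile scaling. Slides correlated at 0.88 to 0.90 across genes, and groups did not overlap for 66.5% of genes (chance 10%). Of the heat calls in the 2 genotypes 6921 rose in both (2870 expected), 6347 fell in both (2272 expected) and 43 went opposite ways (5109 expected). The heat responses of WT and xrn4 correlated at 0.93 across genes.

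Small heat shock genes rose in 15 of 16 cases in xrn4 (15 up and 1 down adjusted over the list alone), with a median of 10.43 (adjusted p = 7.61e-15, and adjusted p = 0.0537 with an estimated correlation). Large chaperones rose in 20 of 22 cases (20 adjusted over the list alone), Hsp70b by 9.64, Hop3 by 8.50, HSA32 by 7.82 and CLPB4 by 5.70. Their median was 4.38 (adjusted p = 1.62e-17, and adjusted p = 0.0663 with an estimated correlation). Heat shock factors had 10 up and 4 down of 18 (10 and 4 adjusted over the list alone). HSFA7A rose by 6.75 and AT-HSFB2B by 4.67. Their median was 1.02 (adjusted p = 0.0163, and adjusted p = 0.091 with an estimated correlation). Oxidative genes had 11 up and 3 down of 16 (12 and 4 adjusted over the list alone). APX2 rose by 8.98, MBF1C by 7.01, DREB2A by 6.57 and GolS1 by 6.06. Their median was 0.63 (adjusted p = 0.00103, and adjusted p = 0.091 with an estimated correlation), and -0.00 under quantile scaling (adjusted p = 0.0155) and 0.04 after normexp and quantile (adjusted p = 0.00663). Here too, a rise separate from that of the heat shock lists was not tested. Jasmonate genes rose in 12 of 19 cases (12 adjusted over the list alone). JAZ7 rose by 2.22, JAZ10 by 2.03, TIFY7 by 1.52 and JAZ1 by 0.94. Their median was 0.47 (adjusted p = 0.0163, and adjusted p = 0.247 with an estimated correlation), and 0.36 under quantile scaling (adjusted p = 0.0545). Unfolded protein genes rose in 9 of 15 cases and fell in 2 (9 and 2 adjusted over the list alone). ATERDJ3A was at least 66.1-fold higher and BIP1 rose by 1.72. Their median was 0.43 (adjusted p = 0.0243, and adjusted p = 0.434 with an estimated correlation) and turned to -0.09 under quantile scaling (adjusted p = 0.0691).

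Falling lists in xrn4 were those of cell division, stomata, microRNA targets and RNA decay. Cell-cycle genes fell in 15 of 25 cases and rose in 2 (15 and 2 adjusted over the list alone). CYC1BAT fell by 2.18 and MCM2 by 0.77. Their median was -0.25 (adjusted p = 0.0031, and adjusted p = 0.247 with an estimated correlation). Stomatal genes fell in 5 of 7 cases and rose in 1 (5 and 1 adjusted over the list alone). FMA fell by 1.14, MYB60 by 1.08 and SPCH by 0.82. Their median was -0.82 (adjusted p = 0.0243, and adjusted p = 0.121 with an estimated correlation). MicroRNA targets fell in 32 of 61 cases and rose in 10 (32 and 10 adjusted over the list alone). TCP3 fell by 2.04, HAM1 by 1.48 and TCP4 by 1.41, while AGO2 rose by 2.24. Their median was -0.51 (adjusted p = 0.000353, and adjusted p = 0.121 with an estimated correlation). RNA decay genes fell in 15 of 26 cases and rose in 4 (15 and 4 adjusted over the list alone), and RH8 rose by 2.77 with 2 of 3 unheated arrays measuring it. Their median was -0.37 (adjusted p = 0.0448, and adjusted p = 0.427 with an estimated correlation). The stomatal and RNA decay calls ended under quantile scaling (adjusted p = 0.0711 and 0.0665).

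Photosynthesis genes rose in 28 of 45 cases in heated xrn4 plants and fell in 3 (28 and 3 adjusted over the list alone), with LHCA3 up 0.76, PETE1 up 1.14, PSBY down 1.41 and LHCB2.2 down 1.25. Their median of 0.44 (adjusted p = 0.00724, and adjusted p = 0.673 with an estimated correlation) flipped to -0.39 under quantile scaling (adjusted p = 0.0103) and -0.40 after normexp and quantile (adjusted p = 0.0128). The 8 lists that did not pass were ethylene (adjusted p = 0.59), salicylate (0.233), abscisic acid (0.242), touch (0.0983), auxin (0.0517), clock (0.434), root (0.113) and xylem (0.52). The touch list passed under quantile scaling (median 0.76, adjusted p = 0.0314) and after normexp and quantile (0.73, adjusted p = 0.0176), and the auxin list under median scaling (0.62, adjusted p = 0.0418). Within them ERF6 rose by 1.45, CYP707A3 by 2.62, RD26 by 1.99 and PRR7 by 2.08, and EDF3 fell by 1.78 and RAV1 by 1.3. WRKY54 was at -2.57, PBS3 at -1.7, FRK1 at -1.39 and WRKY70 at 0.91. TCH4 rose by 4.66, RHL41 by 4.1, TCH3 by 3.18 and STZ by 2.23. EXPA18 fell by 1.14 and SCR by 1.1, while XCP2 rose by 0.49 and IRX3 by 0.31.

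**Figure D3:**
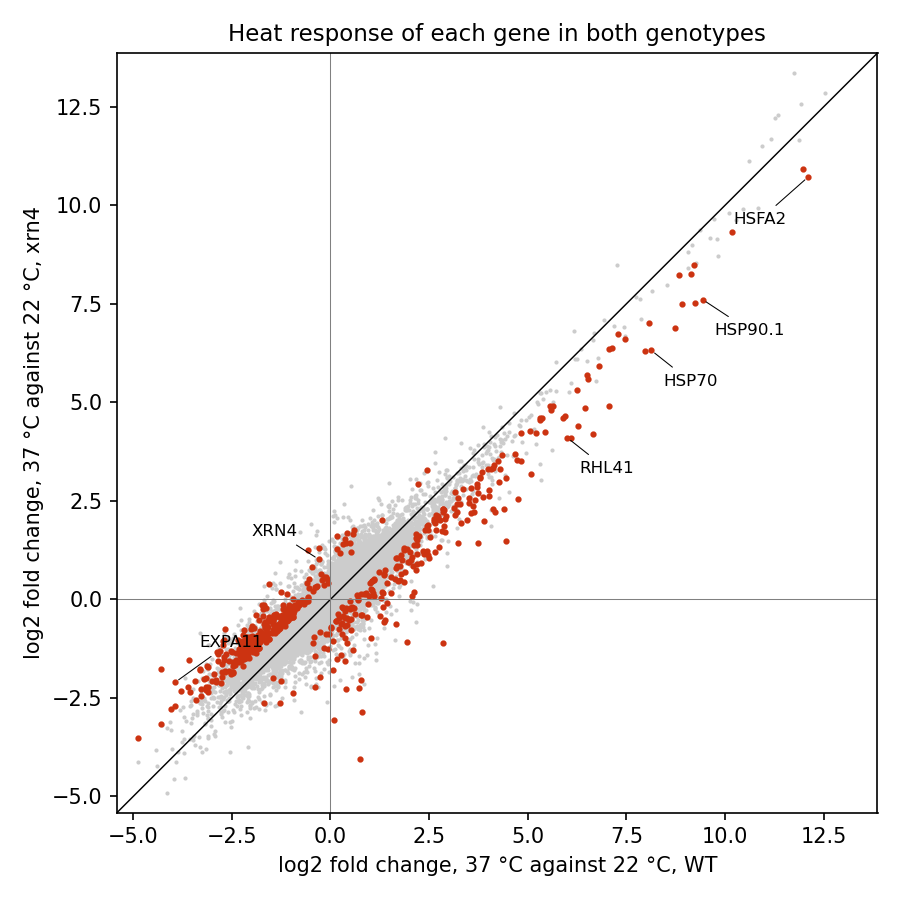
Log2 fold change with heat in xrn4 (vertical axis) against that in WT (horizontal axis) for 24436 genes in grey, with the 543 genes whose heat response differed in red and the line of equal response drawn. Most red points, 433 of 543, have the larger response in WT with the same sign in both genotypes.

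Lists of large chaperones, touch genes and oxidative genes shifted down in the interaction, and single members of these and other lists passed. The interaction, the heat response in xrn4 minus that in WT on the log2 scale, was -1.82 ± 0.16 for HSP90.1 (adjusted p = 0.00216) and -1.81 ± 0.14 for HSP70 (adjusted p = 0.00216). AT3G09440 stood at -1.37 and CLPB4 at -0.80. HSFA2 had an interaction of -1.39 ± 0.23 by its brightest probe (adjusted p = 0.0178) and -0.68 by the mean of its kept probes (adjusted p = 0.143). Over its 11 exon probes the median was -0.56, and 4 passed. For ERF1 the value of -1.56 ± 0.39 did not pass (adjusted p = 0.0728). The zinc finger genes RHL41 and STZ stood at -1.91 and -1.42, and the calmodulin-like genes TCH3 and TCH2 at -1.9 and -1.03. JAZ7 was at -1.95, JAZ5 at -1.45, LOX4 at -1.13, JAZ10 at -0.70, ERF2 at -1.54 and the coactivator gene MBF1C at -1.07. Among small heat shock genes AT5G51440 stood at -1.86, AT1G59860 at -1.05 and AT1G54050 at -0.58.

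The lowest interaction values belonged to AT2G23270 at -4.78 ± 0.64 (adjusted p = 0.00843), AT1G27990 at -3.96, AT2G04070 at -3.65, AT4G14450 at -3.16 and the late embryogenesis gene M17 at -3.03. CHX2, a cation exchanger gene, and BCB, a blue copper protein gene, both stood at -2.97, AT2G01422 at -2.81, AT3G28899 at -2.67 and AT4G19430 at -2.46. The highest were AT2G23200 at 2.54, the receptor kinase gene MRLK at 2.04, AT5G23240 at 1.95, AT5G41280 at 1.93, the expansin gene EXPA11 at 1.83 (adjusted p = 0.0049) and AT1G19420 at 1.82. They were followed by sks15 at 1.68, CYP71A24 at 1.65, AT3G62550 at 1.59 and AT3G55700 at 1.58. ARF17 stood at 1.08, LHCB2.2 at 0.96, MCM2 at 0.58, PSBW at 0.57 and GI at 0.54. An interaction value of a gene that was dim in any group is not a bound and depends on its dim signal.

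The heat response differed between the genotypes for 543 genes, 295 with a positive and 248 with a negative interaction, and 203 by at least 2-fold. With slide as a replicate block 673 passed, 482 of them among the 543. The slides correlated at 0.24 to 0.31 across genes. In 433 of the 543 genes both responses had 1 sign and the WT response was larger, in 29 the xrn4 response was larger, and in 81 the signs were opposite. Of the 543, 222 also differed between the genotypes at 22 °C only, 193 at 37 °C only and 128 at both. Without WT_control replicate 1 the count was 156, with median scaling 326, with normexp and quantile together 1020, without a filter 216 and with a trended robust prior 974.

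Large chaperones had the list interaction with the smallest p, 8 of 22 negative (17 adjusted over the list alone). Their median was -0.59, from -0.67 to -0.52 on the slides (adjusted p = 1.79e-18, and adjusted p = 0.0391 with an estimated correlation). Touch genes, 5 of 13 negative (9 adjusted over the list alone), had a median of -0.82, between -0.94 and -0.45 on the slides (adjusted p = 3.26e-09, and adjusted p = 0.0391 with an estimated correlation). Oxidative genes, 2 of 16 negative (4 adjusted over the list alone), had a median of -0.36 (adjusted p = 2.99e-06, and adjusted p = 0.0391 with an estimated correlation). These were the 3 of 54 list calls that held with an estimated correlation and no block. The touch and oxidative calls are not independent, as both lists hold RHL41, 1 of the 2 oxidative genes that passed. Whether the oxidative shift is separate from that of the heat shock lists was not tested. With slide as a replicate block and an estimated correlation, large chaperones stayed (adjusted p = 0.0307), and oxidative and touch genes did not (adjusted p = 0.108 and 0.174). That pairing of choices also called 3 heat lists in each genotype. In WT these were small heat shock genes and large chaperones (both adjusted p = 0.0308) and microRNA targets (0.0363), and in xrn4 the same 3 lists (each adjusted p = 0.019).

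Jasmonate genes had 4 of 19 negative (6 negative and 1 positive adjusted over the list alone) and a median of -0.34 (adjusted p = 0.000672, and adjusted p = 0.171 with an estimated correlation). Ethylene genes had 1 of 23 negative (3 negative and 1 positive adjusted over the list alone) and a median of -0.19, which was 0.02 on the first slide (adjusted p = 0.0042, and adjusted p = 0.27 with an estimated correlation). Small heat shock genes had 3 of 16 negative (7 negative and 1 positive adjusted over the list alone) and a median of -0.15 (adjusted p = 0.00701, and adjusted p = 0.371 with an estimated correlation). That call ended under quantile scaling (adjusted p = 0.0572). Photosynthesis genes had 2 of 45 positive (2 adjusted over the list alone) and a median of 0.21 (adjusted p = 2.86e-05, and adjusted p = 0.669 with an estimated correlation). Cell-cycle genes had 1 of 25 positive (4 adjusted over the list alone) and a median of 0.17 (adjusted p = 0.000672, and adjusted p = 0.27 with an estimated correlation). Root markers had 0 of 18 past the threshold (1 positive adjusted over the list alone) and a median of 0.19 (adjusted p = 0.0294, and adjusted p = 0.669 with an estimated correlation). The root call ended under quantile scaling as well (adjusted p = 0.0572). The 10 lists that did not pass were heat shock factors (adjusted p = 0.143), unfolded protein (0.929), microRNA targets (0.505), RNA decay (0.387), salicylate (0.387), abscisic acid (0.387), auxin (0.387), clock (0.657), stomata (0.545) and xylem (0.891). The salicylate list passed after normexp and quantile (median -0.10, adjusted p = 0.0157). The xylem median was 0.01 and its mean 0.05, while the test leaned downward.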

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

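The tests of scaling, compression, handling, root share, single repeats and array position, but not those of other splits, were chosen after the results were seen.

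The heat response differed between WT and xrn4 for 543 genes, by a test of the difference itself. With 10 splits of 6 arrays in each pair comparison a share under 0.05 is out of reach. In fits of the 6 arrays alone the labelled split gave 4638, 1874, 16123 and 14241 genes for the genotypes at 22 °C and 37 °C and heat in WT and xrn4, 1 of 10 splits each, and the highest other split gave 0. For the interaction 3 of 100 regroupings of genotype within temperature gave as many genes, the labelled one included, and the highest other gave 1110. These draws ignore the slides and put the genotype difference into the spread within groups. They therefore cannot exclude chance for the count of 543. Of the 32 regroupings that exchange genotypes only within slides, 3 gave as many genes, the labelled one included. That number decides nothing, because 1 of them (7705 genes) exchanged the genotypes on all slides at 1 temperature and so measured the mean genotype difference. Another (1110) kept the genotypes apart at 22 °C only. This does not set it apart, as regroupings with 14, 52, 1, 15 and 71 genes did so too. The remaining 29 gave at most 71 genes, and with a replicate block at most 3. They are those with fewer genes than the labelled one, so their low maximum follows from that choice and decides nothing. With a replicate block the labelled one gave 673 genes. The regroupings set aside, with 7705 and 1110 genes, then gave 9126 and 759.

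The list medians whose interaction passed at the preset correlation were -0.82 for touch genes, -0.59 for large chaperones, -0.36 for oxidative genes, -0.34 for jasmonate genes, -0.19 for ethylene genes, -0.15 for small heat shock genes, 0.17 for cell-cycle genes, 0.19 for root markers and 0.21 for photosynthesis genes. Each was listed because the 2 genotypes differed in their response to heat. With an estimated correlation touch, large chaperone and oxidative genes held (adjusted p = 0.0391 each), and the other 6 did not (0.171 for jasmonate, 0.27 for ethylene and cell cycle, 0.371 for small heat shock, 0.669 for root and photosynthesis). With a replicate block as well, touch (0.174) and oxidative genes (0.108) did not hold. The touch and oxidative lists share RHL41. The single genes whose heat response differed are given as interaction log2 values. Values of genes dim in any group depend on dim signal. AT2G23270, AT4G14450 and CHX2 were well above background in unheated xrn4 plants only, and AT2G04070 on no WT array. Their WT heat responses were thus not measured. No heated WT array measured AT2G23200, MRLK, AT5G23240, AT5G41280 or CYP71A24, and no unheated WT array measured AT1G27990. The focus genes XRN4 and HSFA2 stood at 1.32 and -1.39. XRN4 rests on mutant signals near background. HSFA2 did not pass by the mean of its kept probes, and its 11 exon probes had a median of -0.56. Negative values were held by AT2G23270 (-4.78), AT1G27990 (-3.96), AT2G04070 (-3.65), AT4G14450 (-3.16), M17 (-3.03), CHX2 (-2.97), BCB (-2.97), AT2G01422 (-2.81), AT3G28899 (-2.67), AT4G19430 (-2.46), JAZ7 (-1.95), RHL41 (-1.91), TCH3 (-1.9), AT5G51440 (-1.86), HSP90.1 (-1.82), HSP70 (-1.81), ERF2 (-1.54), JAZ5 (-1.45), STZ (-1.42), AT3G09440 (-1.37), LOX4 (-1.13), MBF1C (-1.07), AT1G59860 (-1.05), TCH2 (-1.03), CLPB4 (-0.80), JAZ10 (-0.70) and AT1G54050 (-0.58). Positive values were held by AT2G23200 (2.54), MRLK (2.04), AT5G23240 (1.95), AT5G41280 (1.93), EXPA11 (1.83), AT1G19420 (1.82), sks15 (1.68), CYP71A24 (1.65), AT3G62550 (1.59), AT3G55700 (1.58), ARF17 (1.08), LHCB2.2 (0.96), MCM2 (0.58), PSBW (0.57) and GI (0.54).

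Probes outside the comparisons of genes carried signal too. Of 245 probes named as tiled on the opposite strand of single genes, 57 were at background on all 6 unheated arrays, and 22 of these were well above it on all 6 heated arrays. Of the 245, 79 were the exact reverse complement of the probe that shares their name, and the strand of the others was not checked. At 22 °C the medians of opposite-strand and exon probes between genotypes were 1.17 and 1.42 for HSP70, but -0.34 and 0.47 for HSFA2. Whether sense transcripts add to the opposite-strand signal was not tested. After heat the median opposite-strand probe rose by 6.96 for HSP70 (13 of 13 probes), 6.89 for HSFA2 (11 of 11), 6.77 for HSP90.1 (17 of 17), 5.33 for HSFA7A (6 of 6), 4.74 for DREB2A (10 of 10), 3.36 for HSP81-3 (16 of 16), 2.68 for NCED3 (11 of 12), 2.09 for HSFA3 (7 of 7) and 1.78 for Hsp70-2 (12 of 14) in WT. It was 0.69 for LTI65 (5 of 11 higher), 0.26 for DREB1A (0 of 2) and -0.12 for RD20 (1 of 13 higher), and for LTI78 it was -0.80 (10 of 15 lower, 1 higher). Of 19206 probes that name no locus 11011 were kept. Heat raised 4921 of them in WT and lowered 899, and 137 were higher and 295 lower in xrn4 at 22 °C. These counts were made under percentile scaling only. For genes, the rising share with heat in WT went from 52.3% to 36.6% under quantile scaling. Whether the excess of rising probes depends on scaling was not tested.

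The salicylate list shifted up in xrn4 at both temperatures, with 11 and 8 of 16 genes higher, though neither call held with an estimated correlation (adjusted p = 0.117 and 0.263). Plants of a single odd repeat are argued against, since the lowest within-slide median of the salicylate list over 3 slides and both temperatures was 0.98. Array position stays open: 0 groups occurred at more than 1 position, so position and genotype cannot be told apart. The mutation itself, named by the design, also stays open and was not tested apart from growth conditions of the plants.

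In the interaction 8 of 22 large chaperones and 5 of 13 touch genes responded less to heat in xrn4. The list medians against WT were 0.28 and 0.52 at 22 °C and -0.32 and -0.25 at 37 °C, where the touch list did not pass (adjusted p = 0.242) and the chaperone call ended under quantile scaling (adjusted p = 0.06). Scaling of the arrays is argued against, as the large chaperone interaction closest to 0 over 3 other scalings was -0.34. Compression of bright signals at 37 °C cannot be told apart from a biological limit, although 0 spots were saturated. The 10 chaperones higher at 22 °C had a median at 37 °C of -0.20 and, over 4 scalings, as close to 0 as -0.035. The SE of that median, 0.0987, measures the scatter among these genes and not among arrays. Genes are not independent replicates, so it does not show how far the median would vary between plants. Different handling or stress of the unheated plants stays open: the lowest within-slide touch median at 22 °C was 0.58, but that rise is part of the pattern and decides nothing, and the missing nuclease stays open too, untested.

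At 22 °C 10 of 18 root markers and 20 of 45 photosynthesis genes were lower in xrn4, and neither list call held with an estimated correlation (adjusted p = 0.178 and 0.317). A lower share of root in the xrn4 samples stays open for the root markers: 18 of 18 measured markers had a lower value, but that is the pattern itself and decides nothing. For the photosynthesis genes a lower share of root is argued against, because less root would raise them and the highest within-slide median was -0.34. A slower growth of the mutant stays open as an untested biological explanation.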

How the results depend on the processing

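The fit that adds probes naming no locus was chosen after seeing the data. XRN4 stayed lower in xrn4 in every alternative that gave it a value: -4.90 to -4.61 at 22 °C and -3.54 to -3.33 at 37 °C with arrays left out, and -2.28 and -1.96 after normexp and quantile. Under the filter for probes well above background on all 12 arrays it has no value. Most counts of genes stayed within 1.5 times their value. The exceptions are named here, and unless stated otherwise the cause was not tested.

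A 2-fold minimum, by its construction, left 850, 602, 5200, 4563 and 203 genes (genotype at 22 °C, at 37 °C, heat in WT, heat in xrn4, interaction). The genotype difference at 37 °C fell from 4142 to 1874 genes in the fit of its 6 arrays, which has fewer samples. The interaction count of 543 became 326 with median scaling, 1020 with normexp and quantile, 216 without a filter, 974 with trend and robust options and 291 together with probes that name no locus. Of 54 list calls 3 held with an estimated correlation.

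With each array left out the counts were 3089 to 4970 at 22 °C, 2487 to 4111 at 37 °C, 14843 to 16398 for heat in WT, 13628 to 15419 for heat in xrn4 and 156 to 564 for the interaction. Single arrays mattered at 22 °C (3149 without WT_control replicate 1, 3089 without WT_control replicate 2, 3239 without xrn4_control replicate 1) and at 37 °C (2487 without WT_heat replicate 3, 2560 without xrn4_heat replicate 1). For the interaction the counts were 156, 267 and 202 without WT_control replicates 1, 2 and 3, 270 without xrn4_control replicate 2, 227 and 314 without WT_heat replicates 2 and 3, and 295 and 327 without xrn4_heat replicates 2 and 3. These fits have fewer samples, and what else set their size was not tested. List calls numbered 50 to 54.

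Directions reversed for XCP2 with heat in WT (-0.0045 after normexp and quantile), for photosynthesis genes at 37 °C between genotypes (0.031 under quantile, 0.040 after normexp and quantile) and for photosynthesis genes with heat in xrn4 (-0.386 and -0.400). With heat in xrn4 the median, though not the direction of the test, also turned for unfolded protein genes (-0.09 under quantile, -0.07 after normexp and quantile) and oxidative genes (-0.001 under quantile). The cause was not tested. Of 54 list calls 39 held under quantile scaling, 45 under normexp and quantile, 54 under median scaling, 47 under the strict filter and 52 with the replicate block. Outside the 2-fold minimum and the fits with an array left out, named genes that passed kept their call in every alternative run in 85 of 92 cases at 22 °C, 51 of 86 at 37 °C, 91 of 93 for heat in WT, 88 of 95 for heat in xrn4 and 23 of 44 for the interaction. With each array left out the numbers were 82, 63, 92, 93 and 23.

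A slide block was not run apart, since it equals the replicate number. Signal over background limits the folds: 58.5 to 72.9% of spots were well above it, and genes below it in 1 group have bounds or depend on dim signal.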

Other observations

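The tests on HSP90.1 introns, iron genes and neighbouring loci were chosen after the results were seen.

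The arrays carry probes tiled along HSP90.1. At 22 °C all 17 exon probes passed as higher in xrn4, with a median of 1.2 (0.64 to 1.62). A rise in transcription might raise intron signal as well, but the median was -0.38 over the 3 intron probes well above background on every unheated array. Over all 4 kept intron probes the median was -0.40, and 1 passed as lower. This decides little, since the intron level in unheated WT was -2.95, near the opposite-strand level of -3.87, against -1.07 for exons. Heat in WT raised the introns by 4.97 and the exons by 9.32. Introns of other tiled genes went both ways. Their medians at 22 °C were 0.66 for HSP81-3 (3 probes), 0.12 for HSFA3 (2) and -0.255 for DREB2A (2). They were -0.31 for HSP70 (2), -0.45 for HSFA2 (2) and -0.84 for HSFA7A (3), and none of the probes of these genes passed. For other tiled genes the exon median at 22 °C was 1.42 for HSP70 (13 of 13 higher), 1.39 for RD20 (13 of 14) and 1.12 for LTI65 (4 of 6). It was 0.86 for HSP81-3 (13 of 14), 0.58 for Hsp70-2 (9 of 14), 0.47 for HSFA2 (4 of 11) and -0.34 for HSFA7A (4 of 6 lower). The median was -0.45 for NCED3 (1 of 10 lower), -0.41 for DREB1A, -0.17 for LTI78 and HSFA3 and -0.14 for DREB2A (1 of 10 lower).

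Iron genes were chosen after their values were seen. At 22 °C and 37 °C the ferritin genes FER1 (-1.48 and -2.2), FER4 (-1.35 and -1.1) and FER3 (-0.64 and -1.23), NEET (-2.11 and -1.82) and the vacuolar transporter-like genes AT1G21140 (-1.51 and -1.41) and AT3G25190 (-1.18 and -1.34) were lower in xrn4, and the factors bHLH38 (2.51 and 1.86) and bHLH39 (2.32 and 1.93) higher. An iron deficiency response that includes root iron uptake stays open. The higher of the IRT1 and FRO2 values at 22 °C was -0.23 (adjusted p = 0.51 and 0.237), and at 37 °C they were 0.49 and 0.09 (0.158 and 0.841). Both are expressed in roots, and root markers had a median of -0.67 at 22 °C, so a lower share of root may mask a rise.

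Neighbours were defined among the kept loci only, so loci that were not kept may lie between them. Of 41 genes at least 2-fold lower in xrn4 at both temperatures, 2 pairs were neighbours on a chromosome, AT1G67105 with AT1G67110 and AT5G46890 with AT5G46900. Among 100 shuffles 0 gave as many pairs and the highest gave 1. A change shared by neighbouring loci, such as a linked difference between the lines, may underlie these 2 pairs. The shuffles treat neighbouring genes as unrelated, so they cannot tell a linked difference from other reasons for neighbours to change together. Of the kept loci next to XRN4, AT1G54500 stood at -0.88 at 22 °C (adjusted p = 0.000775) and -0.76 at 37 °C (adjusted p = 0.00204). The next kept locus on the other side of XRN4, AT1G54460, stood at 0.10 at 22 °C (adjusted p = 0.41) and 0.41 at 37 °C (adjusted p = 0.00682).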
